A study of Mus musculus with 6 samples.

How the data were processed

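RNA of MC3T3 cells, a mouse pre-osteoblast line, was sequenced in 6 libraries. Of these, 3 came from a control group, as the titles call it, and 3 from cells given exosomes of human umbilical vein endothelial cells (HUVEC) for 48 hours. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a SMARTer mRNA sequencing kit. Groups and replicate numbers were taken from the sample titles. The titles call the libraries biological repeats without saying whether they came from separate cultures, so the p-values measure the spread between these libraries.

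The deposited values were FPKM (fragments scaled to exon length and library size), per the name of the deposited file, with 1 column per library. The same name says that the genes listed were those the authors had called changed, so the 680 genes tested here were chosen on these same libraries. Counts of calls are therefore not independent evidence that genes differ, and no expressed background for an enrichment test was used. The aligner, read counter, genome build, annotation, caller and threshold of the authors were not given in the sources used here.

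Gene symbols, classes, exon lengths and positions were looked up by gene identifier in GENCODE M21 (GRCm38), which matched 672 of the 680 identifiers. The other 8 are given by identifier in the tables and entered the tests. The authors' own build may differ, so positions printed are those of GRCm38. Multiplying FPKM by the summed exon length gave whole multiples of 1 step, within 0.02 reads, in all 6 libraries for 661 of the 672 matched genes. The step gives the depth of each library: 39630444, 43570888 and 48369052 reads in the control libraries and 52125805, 54429032 and 51315986 in the exosome libraries. Of 1691 recovered values from 2 to 21 reads, 74.7% were even, the pattern left when both mates of a pair are counted, so counting errors are larger than the read numbers imply. The median gene had 16, 19 and 18 reads in the control libraries and 12 in each exosome library.

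The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on log2(FPKM + 1), two-sided, with the group as its only term and Benjamini-Hochberg adjustment over the 680 genes. The threshold was an adjusted p under 0.05. Genes the authors did not list are missing from this adjustment, and the listed ones were selected on the same libraries. Each limma adjusted p given here is therefore too small as a measure of significance. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes, and folds are ratios of mean FPKM. The test, the alternatives, 19 gene lists and the rule for named genes were fixed before the data were examined. The rule names Creld2, Atf4 and Eif2ak3 from the series title. It adds the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap and a mean of at least 1 FPKM in the higher group, leaving out unnamed models, pseudogenes and Y-linked genes. It also takes up to 4 members of each list by adjusted p and the 5 genes of highest mean FPKM.

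The lists were PERK-ATF4 targets, ER folding and ER-associated degradation, osteoblast differentiation and mineralisation, secreted angiogenic and vascular factors, interferon response, NF-kB and inflammatory mediators, cell cycle, extracellular matrix and contractile genes, hypoxia and glycolysis, cholesterol and fatty acid synthesis, oxidative stress response, mitochondrially encoded genes, BMP, Wnt and Notch pathway genes, immediate early and heat shock genes, and markers of endothelial, macrophage and leukocyte, adipocyte, muscle and cartilage cells. List sizes count symbols, and some genes were entered under both an older and a newer name, so the sizes overstate the numbers of genes. Lists with at least 3 genes analysed were tested by a two-sided Fisher's exact test of higher against lower, set against the other genes of the table, and by limma's fry. Each was adjusted over the 3 lists tested. A pass adjusted over the list alone refers to the limma p of a gene, adjusted over the members analysed. With 1 member analysed this is the unadjusted p. fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. All members analysed had been selected by the authors as changed on these libraries. A fry pass was therefore likely beforehand and is not independent evidence.

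The alternatives were pseudocounts of 0.1 and 0.01, genes with a mean of at least 1 FPKM, centring each library on its median, a replicate block, a trended and robust prior, a 2-fold limit, and leaving out each library in turn. A limma-voom fit to the recovered reads was added after seeing the data. Annotated gene classes, an epithelial gene list and the position of loci inside other genes were also taken up after seeing the data. Fisher's exact tests, chi-square tests and Wilson intervals were computed with scipy 1.17.1 and statsmodels 0.14.6. They cover counting error only.

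The script was tested on simulated reads for 661 genes with the recovered depths, with 200 genes changed in silico. In the simulated exosome comparison, a 2-fold change was recovered for 19 of 23 genes with a mean of at least 1 FPKM and for 21 of 77 below it. A 4-fold change was recovered for 19 of 20 and 44 of 80, and 4 of 461 unchanged genes were called. Reads were simulated singly, with 1 dispersion for all genes, whereas the real counts look as if both mates were counted. That difference would overstate the recovery of weakly expressed genes. Only 200 of the 661 simulated genes were changed, whereas the real genes had all been selected as changed. This made the adjustment stricter in the simulation, which acts the other way. The simulated rates of recovery and of false calls may therefore not hold for the real genes. No library duplicated another of its group, with a chi-square per degree of freedom between 24.8 and 59.5 for the pairs. Whether the replicate numbers pair the libraries could not be decided, as described with the alternatives.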

Results

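The comparison asked how exosomes from HUVEC, a primary human endothelial cell, alter gene expression in the mouse pre-osteoblast line MC3T3, in a series whose title names the PERK-ATF4-CRELD2 pathway. Exosomes are small membrane vesicles that cells release. RNA sequencing covered 3 control and 3 exosome-treated libraries of 39630444 to 54429032 reads, and the mean depth of the exosome group was 1.20 times that of the control group. FPKM values of 680 genes were analysed, all of them selected by the authors as changed in these libraries. The limma adjusted p-values below do not account for that selection and are too small. Of the 680 genes, 177 had the higher mean with exosomes and 503 the lower, so 26.0% were higher (Wilson 95% interval 22.9 to 29.5). Among the 138 genes with a mean of at least 1 FPKM, 61 were higher and 77 lower, while below that level 116 were higher and 426 lower.

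Creld2, the endoplasmic reticulum (ER) protein of the series title, rose 2.50-fold with exosomes, from 174 ± 72.0 to 436 ± 10.8 FPKM (SD, n = 3 per group). It lies on chromosome 15 from 88819646 to 88826683 in GRCm38. The rise was 1.40 ± 0.29 on the log2 scale (SE, limma adjusted p = 0.0178). Further genes of the ER folding list rose with it. Manf, a secreted protein induced by ER stress, went from 124 ± 37.3 to 296 ± 15.6 FPKM (limma adjusted p = 0.0129). Sdf2l1, a component of ER chaperone complexes, went from 65.0 ± 23.9 to 162 ± 17.7 (limma adjusted p = 0.0161). Dnajc3, an ER co-chaperone that inhibits PERK, went from 51.2 ± 19.6 to 103 ± 12.0 (limma adjusted p = 0.0321). The control libraries spread more widely than the exosome libraries in Creld2, at 155, 114 and 254 against 443, 441 and 423 FPKM. Among the control libraries, Creld2, Manf, Sdf2l1 and Dnajc3 were each lowest in library 2 and highest in library 3, so they did not vary independently. All 4 list members analysed of 33 rose, and 4 also passed adjusted over the list alone, which is not independent evidence because the authors chose the genes on these libraries. These 4 members were higher more often than the other genes (Fisher's exact adjusted p = 0.0134), by a test that counts genes moving together as independent. They moved upward by fry (limma fry adjusted p = 0.0123, median log2 difference 1.32), a pass that their selection as changed made likely beforehand. Without exosome library 1, 2 or 3 the limma adjusted p of Creld2 was 0.0512, 0.0571 and 0.0526, and that of Dnajc3 0.0864, 0.0713 and 0.0874, with 0.0755 for Dnajc3 without control library 1. Sdf2l1 reached 0.0525 and 0.0516 without exosome library 2 or 3 (limma adjusted p), and the Fisher's exact adjusted p of the list was 0.0722 among genes with a mean of at least 1 FPKM and 0.190 after median centring, which itself sets how many of the other genes are higher.

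**Figure D1:**
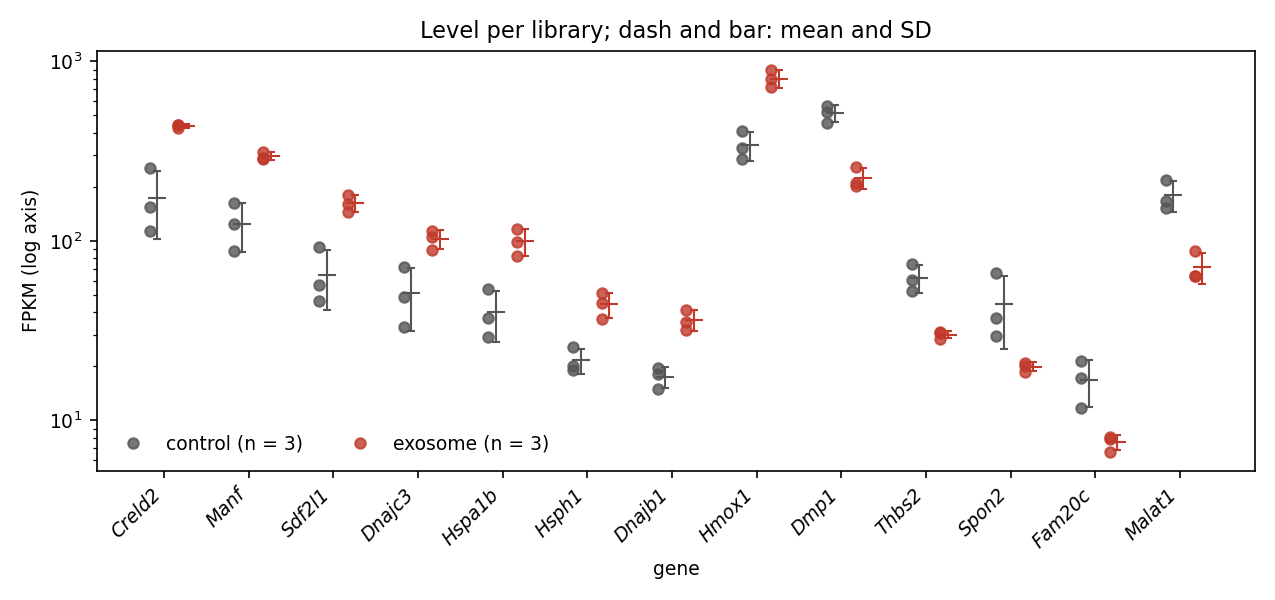
FPKM of 13 genes in each library on a log axis, with control libraries in grey and exosome libraries in red, 3 per group; the dash and bar give the mean and SD. Creld2 lies at 114 to 254 FPKM in the control libraries and at 423 to 443 in the exosome libraries, while Dmp1 is lower in every exosome library.

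Atf4 and Eif2ak3, which encodes PERK, are not among the 680 genes analysed here. Of the 48 symbols in the PERK-ATF4 target list, which include Atf4 and Eif2ak3 and older and newer names of some genes, 1 was analysed. That gene, the cationic amino acid transporter Slc7a3, fell from 1.65 ± 0.244 to 0.798 ± 0.0602 FPKM (SD, n = 3; limma adjusted p = 0.00634). It also passed over the list alone, where its p is unadjusted.

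Genes of the oxidative stress and heat shock lists rose as well. Hmox1, the heme-degrading enzyme of the oxidative stress list, had the highest mean level in the table and went from 341 ± 62.1 to 803 ± 90.8 FPKM, a 2.35-fold rise (SD, n = 3 per group; limma adjusted p = 0.00634). It lies on chromosome 8 from 75093621 to 75100589 in GRCm38. As the only gene of 29 in its list analysed, it also passed over the list alone, where its p is unadjusted. Of the immediate early and heat shock list, the cytosolic chaperone genes Hspa1b, Hsph1 and Dnajb1 rose. Hspa1b went from 40.1 ± 12.6 to 99.5 ± 17.1 FPKM (limma adjusted p = 0.0160), and reads of Hspa1b cannot be separated with certainty from those of its near-identical neighbour Hspa1a. Hsph1 went from 21.6 to 44.3 FPKM and Dnajb1 from 17.5 to 36.2. The fourth member analysed, the transcription factor gene Egr2, had 4.45 ± 2.20 FPKM in control and 1.97 ± 0.278 in exosome libraries (limma adjusted p = 0.0692). It passed with pseudocounts of 0.1 and 0.01, among genes with a mean of at least 1 FPKM, without control library 3 and by limma-voom (limma adjusted p = 0.0350, 0.0478, 0.0315, 0.0243 and 0.0196). Adjusted over the list alone, 4 of 4 passed, against 3 over all genes. By fry the 4 genes analysed, of 28 in the list, moved upward (limma fry adjusted p = 0.00681), a pass that their selection as changed made likely beforehand. The test of their direction against the other genes did not pass (Fisher's exact adjusted p = 0.0843).

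Other large rises were in Selenok, an ER membrane selenoprotein, from 21.2 to 43.7 FPKM, in the SCAN domain gene Scand1, from 3.04 to 7.37, in the ribosomal protein gene Rps27, from 27.4 to 85.1, and in the short non-coding RNA gene Bc1, from 2.51 ± 1.71 to 20.9 ± 10.7. Rps27 and Bc1 have many genomic copies, so their counts are uncertain. Scand1 lost its call without control library 1 or 3 or exosome library 2 or 3 (limma adjusted p between 0.0562 and 0.0698), and Bc1 without control library 2 or exosome library 2 or 3 (0.0507 to 0.0625).

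Dmp1, an acidic phosphoprotein of bone matrix and the only gene of 34 in the osteoblast list analysed, fell 2.29-fold from 514 ± 55.3 to 224 ± 29.5 FPKM (SD, n = 3 per group). This was −1.19 ± 0.12 on the log2 scale (SE, limma adjusted p = 0.00512), and it also passed over the list alone, where its p is unadjusted. Dmp1 lies on chromosome 5 from 104202613 to 104214102 in GRCm38. Fam20c, the Golgi kinase that phosphorylates such proteins, went from 16.8 ± 4.88 to 7.54 ± 0.737 FPKM (limma adjusted p = 0.0183), a call lost when any 1 of the exosome libraries was left out (0.0526 to 0.0556). The extracellular matrix genes Spon2 and Sned1 fell from 44.4 to 19.9 and from 7.06 to 2.19 FPKM, and the membrane protein gene Lrrc15 from 5.99 to 2.40. Nav2, of the neuron navigator family, fell from 6.66 to 2.54. Spon2 lost its call after median centring (limma adjusted p = 0.0513) and when control library 1 or any exosome library was left out (0.0660 to 0.0926).

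The extracellular matrix and contractile list had 4 of 46 genes analysed, and Actg2, Cnn1, Itga11 and Prelp all fell, with 4 passing adjusted over the list alone. Actg2, a smooth muscle actin, went from 1.03 to 0.450 FPKM, and Prelp, Itga11 and Cnn1 started from 0.310, 0.413 and 0.414 FPKM. These 4 genes moved downward by fry (limma fry adjusted p = 0.00681, median log2 difference −0.26), a pass that their selection as changed made likely beforehand. The test of their direction against the other genes did not pass (Fisher's exact adjusted p = 0.577). Median centring, which adds 0.15 to every log2 difference, ended the calls of Prelp, Itga11 and Cnn1 (limma adjusted p = 0.488, 0.143 and 0.0762), whose log2 differences were −0.19, −0.25 and −0.28 before and −0.05, −0.10 and −0.13 after it. Actg2 reached 0.0556 without exosome library 2, Itga11 0.0564 and 0.0565 without exosome library 2 or 3, and Prelp 0.0512 to 0.111 without control library 2 or 3 or any exosome library (limma adjusted p).

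Of 34 secreted angiogenic and vascular factors, 2 were analysed, and both fell and passed adjusted over the list alone. Thbs2, a thrombospondin that restrains angiogenesis, went from 62.3 ± 10.8 to 30.0 ± 1.39 FPKM (SD, n = 3; limma adjusted p = 0.00634). The chemokine gene Cxcl12 went from 1.86 ± 0.545 to 0.775 ± 0.143 (limma adjusted p = 0.0227), a call lost when control library 1 or any exosome library was left out (0.0526 to 0.0680). The receptor gene Notch1 was the only gene analysed from the 46 BMP, Wnt and Notch genes. It fell from 4.89 to 2.22 FPKM (limma adjusted p = 0.00849) and also passed over the list alone, where its p is unadjusted.

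Il33, the only inflammatory mediator of 33 analysed, went from 0.295 to 0.140 FPKM (limma adjusted p = 0.0297), and the cartilage gene Col11a2, the only 1 of 19, from 0.232 to 0.0902 (limma adjusted p = 0.0311). Both also passed over the list alone, where each p is unadjusted. Il33 and Col11a2, each with a log2 difference of −0.18 against the 0.15 that median centring adds, had limma adjusted p values of 0.551 and 0.598 after it, and of 0.0587 to 0.0831 and 0.0657 to 0.0909 in leave-one-out fits, except that Il33 kept its call without control library 1 and Col11a2 without control library 3. Ifit1bl1, the only interferon response gene of 47 analysed, was listed at 0 in every control library and at 0.0451 ± 0.0109 FPKM in the exosome libraries (SD, n = 3; limma adjusted p = 0.0543). It passed adjusted over the list alone, with pseudocounts of 0.1 and 0.01, after median centring and by limma-voom (limma adjusted p = 0.0177, 0.00178, 0.00591 and 0.00263 in the last 4). These calls rest on only 6, 4 and 6 reads, against control values that are all 0 and so have no spread. Car12, the only hypoxia and glycolysis gene of 35, had 0.0588 against 0.0193 FPKM and Actc1, the only muscle marker of 17, had 0.0303 against 0.154 (limma adjusted p = 0.135 and 0.173), and neither passed adjusted over the list alone. Car12 passed with a pseudocount of 0.01 and by limma-voom (limma adjusted p = 0.0326 and 0.0339), and Actc1 after median centring and by limma-voom (0.0410 and 0.0453). The exosome mean of Actc1 rests on library 1, at 0.320 against 0.0681 and 0.0723 FPKM. Its log2 difference of 0.156 was 0.0553 without that library. The log2 differences of Ifit1bl1 and Actc1 were 0.0635 and 0.156 before centring added its 0.15, so their calls after it rest largely on that shift. The mitochondrial genes mt-Atp8 and mt-Nd4l, 2 of 13, overlap neighbouring genes and had 54.3 ± 51.7 against 339 ± 436 and 41.2 ± 14.7 against 153 ± 85.9 FPKM (limma adjusted p = 0.157 and 0.0555). The exosome mean of mt-Atp8 rests on library 1, at 842 against 116 and 60.3 FPKM, and its log2 difference of 2.20 was 1.10 without that library and 1.47 without control library 2. mt-Nd4l passed with pseudocounts of 0.1 and 0.01, among genes with a mean of at least 1 FPKM, after median centring, with the replicate block, without exosome library 2 and by limma-voom (limma adjusted p = 0.0249, 0.0294, 0.0172, 0.0484, 0.0452, 0.0262 and 0.0130). None of the 47 cell cycle, 21 endothelial, 18 macrophage and leukocyte or 15 adipocyte genes is among the 680 genes analysed here. In all, 26 of 596 list symbols were analysed and 20 passed over all genes tested.

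Several non-coding RNA genes fell. Malat1, an abundant nuclear RNA, fell 2.50-fold from 179 ± 35.4 to 71.9 ± 14.1 FPKM (SD, n = 3 per group; limma adjusted p = 0.00897) and lies on chromosome 19 from 5795690 to 5802672 in GRCm38. Small RNA loci inside other genes fell too. Snord59a went from 5.02 ± 1.86 to 0.997 ± 1.51 FPKM, Mir5125 from 208 ± 45.5 to 91.2 ± 37.7, and Mir1970 from 7.50 ± 0.876 to 3.31 ± 2.03 (limma adjusted p = 0.0403, 0.0294 and 0.0395). Snord59a rests on only 21, 12 and 15 reads in the control libraries and 1, 11 and 0 in the exosome libraries. Mir1970 had 35, 31 and 36 against 11, 32 and 12 reads. Reads at such loci can come from the surrounding gene. The calls of Snord59a and Mir1970 were lost after median centring (limma adjusted p = 0.0563 and 0.0662) and when any library other than exosome library 2 was left out (0.0791 to 0.108 and 0.0837 to 0.107). Mir5125 lost its call without control library 2 or 3 or exosome library 1 or 2 (0.0667 to 0.0807). By annotated class, chosen after seeing the data, 233 of 334 protein-coding genes were lower (69.8%). Loci awaiting experimental evidence (TEC) were lower in 83 of 90 cases and antisense loci in 58 of 66 (Fisher's exact adjusted p = 4.55e-05 and 0.00749 against coding genes, 10 classes tested). Most TEC loci lie inside another gene. Of all non-coding loci, 136 of 140 inside another gene were lower and 72 of 108 outside, so class and position were not told apart. Whether reads were assigned by strand was not given in the sources used, so reads of antisense loci can come from the gene on the other strand. The 6 lncRNAs of bidirectional promoters were all higher (Fisher's exact adjusted p = 0.00440). After median centring 132 of 334 coding genes, 40 of 90 TEC loci and 45 of 66 antisense loci were lower, but 118, 41 and 16 of these classes have a control level below the 0.15 that centring adds and are higher after it at any fold.

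**Figure D2:**
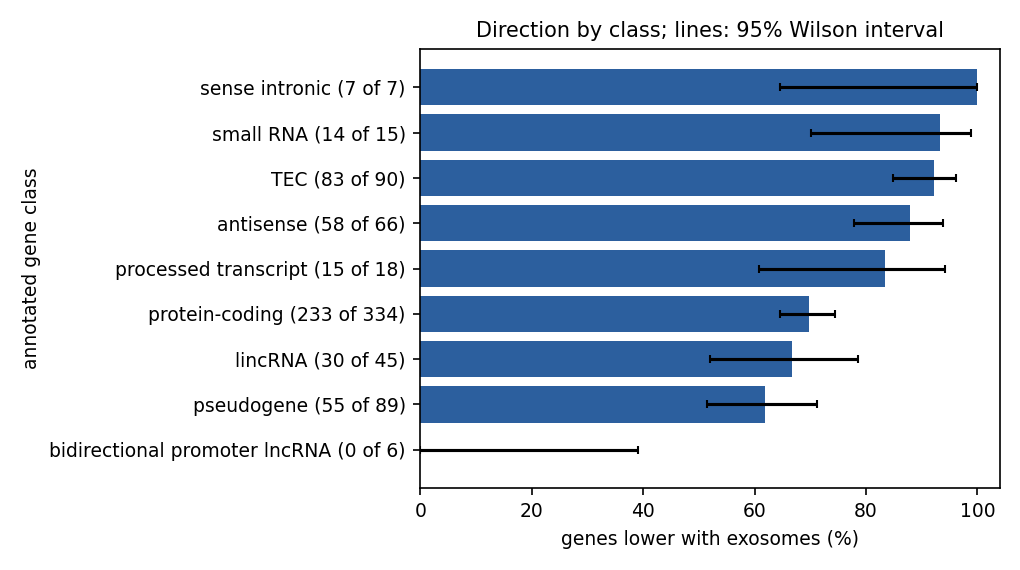
Share of genes with a lower mean FPKM in the exosome libraries for each annotated class, with 95% Wilson intervals as lines and counts in brackets. TEC loci reach 92.2% and protein-coding genes 69.8%.

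Over the whole table, limma called 403 genes, 105 higher and 298 lower. The groups did not overlap in 591 genes (86.9%, against 10% by chance), all of them selected on these libraries. The median of log2(FPKM + 1) was 0.29 in the control and 0.15 in the exosome libraries, a shift of −0.15. After centring on these medians, which come from selected genes, 324 genes passed, 212 higher and 112 lower. Relative to that shift Creld2 was higher by 1.54, Hmox1 by 1.39, and Dmp1 and Malat1 differed by −1.05 and −1.16 on the log2 scale. Without exosome library 1, 2 or 3, limma called 237, 164 and 184 genes. With a replicate block, Bc1, Cxcl12, Il33, Spon2 and Mir5125 (limma adjusted p = 0.0660, 0.0660, 0.0660, 0.0668 and 0.0687) and Mir1970, Snord59a, Col11a2 and Prelp (0.0846, 0.0860, 0.0944 and 0.115) lost their calls. Whether the replicate numbers pair the libraries is not known.

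**Figure D3:**
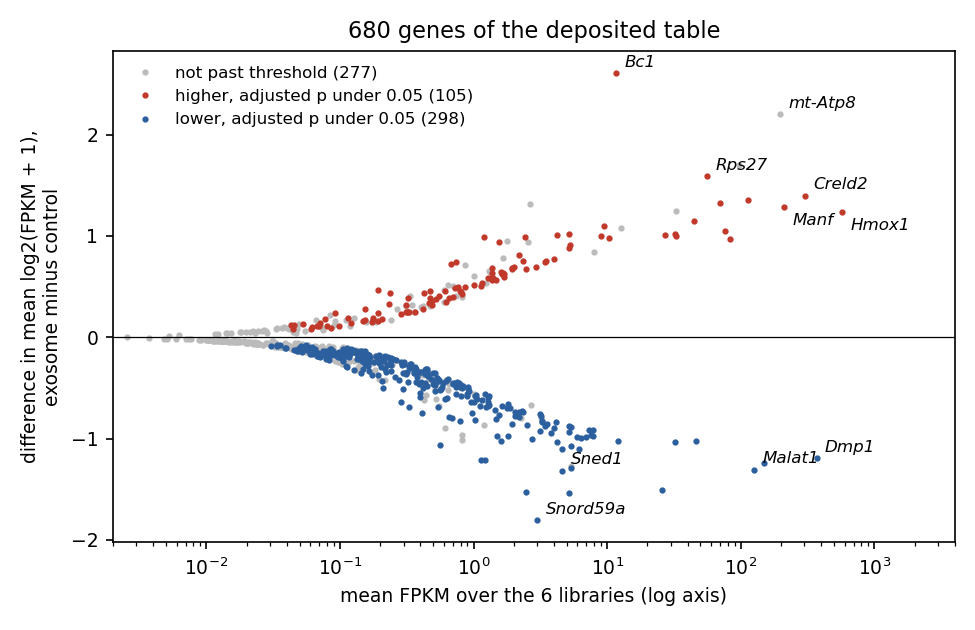
Difference in mean log2(FPKM + 1), exosome minus control, against mean FPKM on a log axis for 680 genes, each point a gene. The 105 genes past the limma threshold with higher values are red, the 298 lower ones blue and the remaining 277 grey.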

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

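The limma-voom fit was chosen after seeing the data; the other alternatives were not. The main count of 403 genes (105 higher, 298 lower) stayed within 1.5 times with a pseudocount of 0.1 (528), a trended and robust prior (550) and a 2-fold limit (390). It was 611 (455 lower) with a pseudocount of 0.01 and 624 (472 lower) with limma-voom on recovered reads, sharing 401 and 387 genes with the main 403. It was 131 (56 higher, 75 lower) among genes with a mean of at least 1 FPKM, where fewer genes were tested. Median centring gave 212 higher and 112 lower and took the share of higher genes from 26.0% to 52.9%, a balance that centring on these genes fixes; it was 44.2% with the FPKM limit. Leaving out 1 library gave 164 to 356 genes, 48 to 78 higher and 116 to 280 lower, with fewer samples. The replicate block gave 201 genes (54 higher, 147 lower), 197 of them shared. Same-numbered libraries deviated with correlations of −0.135, 0.0767 and −0.222. These show no pairing but cannot exclude it, because they come from selected and mostly weakly expressed genes. The Fisher's exact adjusted p of the ER folding list was 0.0722 with the FPKM limit and 0.190 after centring, the range over its alternatives being 0.0134 to 0.190. The fry calls of the 3 lists held where run (highest limma fry adjusted p = 0.0455), which is not independent support because all members analysed had been selected as changed. The fry test was not run with the 2-fold limit, nor for the extracellular matrix list with the FPKM limit, and does not use the prior. For the 39 named genes the trended and robust prior and the 2-fold limit were not tallied. In the other alternatives run, 17 kept their direction and stayed called or not called as in the main test. Of the 33 called, 17 lost the call somewhere, and 5 of the 6 not called passed somewhere. Car12, not called, turned to 0.0917 on the log2 scale after centring, which adds more than its whole level. Where not stated, the cause was not tested. Depth limits weak genes: 190 to 306 of 661 had under 10 reads per library.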

Other observations

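The tests over other splits of the libraries, of uniform DNA and of epithelial genes, and the families named here, were chosen after the results were seen; those of host genes and of expression level were set down before their results.

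Clustered protocadherins, cell adhesion genes, were lower in 8 of 8 cases analysed, and 4 of these fell past the limma threshold, among them Pcdhb21 from 1.43 to 0.640 FPKM. After median centring 2 of the 8 were lower, but 5 have a control level below what centring adds and are higher after it at any fold. Several share exons, so their counts are uncertain. The related Pcdh18 fell from 10.7 to 4.93 FPKM (limma adjusted p = 0.0143). Small nucleolar, Cajal body and spliceosomal RNA loci were lower in 11 of 12 cases, 11 also after centring, and 8 fell past the threshold. All 12 lie inside another gene, where 136 of 140 non-coding loci were lower, so this share is not particular to these classes. After centring 86 of the 140 were lower, and 45 are higher at any fold. Among coding genes outside the lists, the cell cycle regulator Cdk2ap2 rose from 55.7 to 110 FPKM (limma adjusted p = 0.00634) and Jund, an AP-1 transcription factor gene, from 2.65 to 5.30 (limma adjusted p = 0.0278).

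The number of genes called was set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1, the real one, reached 403 genes, and the highest of the others was 0 by limma (at most 11 genes at an unadjusted p under 0.05, against 478). The genes had been selected for differing between the real groups, so this contrast was set beforehand, and with 10 splits the share cannot go under 0.1, which is too few to decide.

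Non-coding loci were lower more often than coding genes, at 208 of 248 (83.9%) against 69.8%. Not every class shared this, as the lincRNAs among them were lower in 30 of 45 cases (66.7%). Pseudogenes, left out of the 248, were lower in 55 of 89 (61.8%). Low level alone does not account for the excess of the 248 over coding genes, since within 4 strata of mean FPKM the odds ratio of being lower was 2.20 (95% interval 1.45 to 3.33). Loci inside another gene were lower in 136 of 140 cases and those outside in 72 of 108 (66.7%, two-sided Fisher's exact p = 4.25e-11). After median centring 86 and 46 were lower (p = 0.00465, Fisher's exact), where 45 and 40 are higher at any fold because of their low level. A candidate explanation is less unspliced host RNA in the exosome libraries, by the treatment or by RNA preparation, which these data cannot separate. Of the 140, 3 have a host among the 680 genes. Loci on the strand of their host were lower in 81 of 82 cases and those on the opposite strand in 53 of 56. Host RNA could account for the latter only if reads were not assigned by strand, which was not given. DNA carried over in the control libraries stays open too: the median loss in the 52 lower loci of highest level was 34.9 times that in the 52 of lowest level, but the selection on fold ties loss to level, and at these levels the ratio could not have come out under 21.8.

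Epithelial genes were lower in 12 of 12 cases analysed from a list of 50, written after such genes had been seen among the falls, against 185 of 256 other coding genes under 1 FPKM (two-sided Fisher's exact p = 0.0401). Because of how the list was made this comparison cannot be read as evidence of a difference. After median centring 4 of the 12 were lower, and 7 are higher after it at any fold. Lad1, Rab25 and Grb7 passed the limma threshold, and the most abundant, Krt18, had 0.788 against 0.251 FPKM. All 12 were picked by the authors from these libraries, none is in another list, and how many of them MC3T3 cells express was not examined. A trace of epithelial RNA in the control libraries may be a source, with 155, 240 and 243 reads against 117, 41 and 29, but a chi-square test for 1 ratio across the control libraries (p = 0.135) had expected counts under 5 in 14 of 36 cells and leaves this open.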
